A study of Pseudomonas aeruginosa with 6 samples.

How the data were processed

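RNA of Pseudomonas aeruginosa NCTC8626 was compared between cultures grown for 4 h at 37 °C in Mueller-Hinton broth with manuka honey at 10% (w/v) and without it, per the labels' protocols. There were 3 biological replicates per group and 1 array for each. The deposited values are log2 signals per probe set, made with RMA in Affymetrix Expression Console per the submitters' processing notes; software versions and probe set definitions are not given in the sources used here. The log base is not stated and was taken as 2 from the range of the values. RMA corrects background, equalises the distributions of probe signals between arrays and then summarises the probes of each set. The distributions of the summarised values can still differ. A change in total RNA per cell or a shift of most genes in 1 direction would not show in these values. The table held 5896 probe sets, and no 2 arrays were identical.

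A probe set's gene was taken from the platform annotation supplied with the value table, which lists 1 gene symbol for 5500 probe sets, several for 0 and none for 396. All 5500 matched the PAO1 reference annotation (assembly ASM676v1) by gene identifier, and symbols and neighbours were taken from it, without coordinates since the array's build is not given. By their names 5545 probe sets were PAO1 genes, 199 intergenic, 138 from other strains or structural RNAs and 14 foreign-organism controls. The strain differs from PAO1, so a low signal can also come from sequence differences.

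The 14 controls were left out and honey minus control was fitted to the other 5882 probe sets with lmFit and eBayes (limma 3.58.1, R 4.3.3), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The moderated variance had 5.45 prior and 4 residual degrees of freedom. A set of 44 gene lists with 986 members, 30 of them unmatched and 949 list memberships measured, was fixed before the data were examined. Lists were tested with camera at a preset correlation of 0.01 and adjusted over the 44; camera with an estimated correlation and fry were alternatives. A list's members were also adjusted over the list alone. Named genes followed a rule fixed at the same time: the 10 largest rises and 10 largest falls with a symbol among probe sets past the threshold with no overlap between groups, the 3 largest each way with a locus tag only, up to 4 called members of each list or else the values of up to 2, and always oprF, algD, fleQ, fleR, fleN, fliA, flhF and fliC. Only 6 called falls had a symbol, so 22 genes met the first part.

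The background level of an array was its brightest foreign control probe set. A probe set counted as above background when it exceeded that level on all 3 arrays of at least 1 group, a definition chosen after seeing the data. Where such a gene was below the level on every array of the dimmer group, the fold is given as a bound, the bright group's mean against the dim group's mean of, per array, the higher of the level and its own value. Such a bound, written as at least, allows for the background level only. It is not a confidence limit and can be lower when an array is left out. Where neither group was above background on all its arrays, the log2 difference of the signals is given as fitted, with the arrays above background, and is not a measured fold of the transcript.

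The same fit was tested on simulated arrays with 200 changed probe sets among 5882. It recovered 43.3% of those changed by 0.5 log2 units, 92.5% at 1 and 100% at 2, with 8 false calls (4.85% of calls). Camera called 0 of 44 lists in simulated arrays with no effect, and the raised list in arrays where 1 was raised. The probe sets were simulated independently of each other, with no variation shared across an array. These arrays therefore do not show how either test behaves where genes are correlated or whole arrays deviate. The recovery and false calls apply to the simulated setting only.

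Whether the shared replicate numbers pair the cultures was checked before the fits were compared, and they were treated as not pairing them. The alternatives were the replicate number as a block, median centring, cyclic loess, leaving out the dimmest 25% or 50% of probe sets by mean value, an intensity trend with robust variance, array weights, no moderation and leaving out each array in turn. Another 3, chosen after seeing the data, used only probe sets above background, centred on those outside the ribosomal protein list, or left out honey replicate 2 and control replicate 1 together. Figures were drawn with matplotlib 3.10.9.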

Results

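Total RNA from Pseudomonas aeruginosa NCTC8626, a culture-collection strain of an opportunistic human pathogen, was profiled on Affymetrix arrays after 4 h at 37 °C in Mueller-Hinton broth, with or without manuka honey at 10% (w/v). Each group had 3 biological replicates and 1 array per replicate. The 6 arrays carried 5896 probe sets, of which 5882 were tested and 14 foreign-organism control probe sets were left out. The values are log2 RMA signals, and the precision is limited by the number of arrays. Signal was low: array medians lay between 2.34 and 2.39, and the brightest foreign control probe set of an array, used as its background level, lay between 2.46 and 2.99. By that level 997 probe sets (16.95%) were above background on all 3 arrays of at least 1 group, 525 of them in both groups, 404 in honey only and 68 in control only. This split depends on the level of each array: control replicate 2 had the highest level (2.99) and 11.5% of probe sets above it, against 42.9% for control replicate 1 with the lowest (2.46), while the array medians were close to equal. At the bright end the arrays differed: 22, 38 and 28 probe sets had a value above 5 in control replicates 1, 2 and 3. In honey replicates 1, 2 and 3 there were 55, 84 and 52. The 23S ribosomal RNA probe set, the brightest, lay between 14.66 and 14.88 on every array. The first principal component held 52.3% of the variance and separated the groups, with honey replicate 2 farthest out at 19.9 against 5.39 and 3.94 for the other honey arrays.

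The comparison asked how exposure to the honey altered the transcriptome. Of the 53 ribosomal protein probe sets 14 rose in honey and 0 fell, with a list median of 1.00 log2 units. There was 1 rise and a list median of 0.55 under cyclic loess between arrays. On single arrays, the median value of these probe sets ran from 3.37 to 4.30 in control and from 4.37 to 5.55 in honey. In addition, 3 of 11 arginine deiminase and Anr-linked and 2 of 13 NADH dehydrogenase I probe sets rose. All 3 lists were called higher by camera at a preset correlation, and all 3 calls were lost with an estimated one (adjusted p = 0.44 with an estimated correlation). The dhcA, dhcB and atoB cluster, the cold shock gene capB and the flagellar gene fliE fell. PA3309, encoding a universal stress protein, rose 4.80-fold (log2 difference 2.26 ± 0.13, SE, n = 3 per group, limma adjusted p = 8.0e-05), with a log2 difference of 1.49 under cyclic loess. dhcB, encoding a subunit of dehydrocarnitine CoA transferase, was 2.21-fold lower in honey (-1.14 ± 0.13, adjusted p = 0.010).

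In all, 63 probe sets changed at an adjusted p under 0.05, 47 higher and 16 lower in honey. By the difference of group means 25 rose and 4 fell by at least 2-fold, but the bound over background was under 2-fold for 3 of the 25 and 2 of the 4, and 1 of the 25 was not above background. With cyclic loess between arrays in place of the deposited scaling, 29 were called, 15 higher and 14 lower. At an unadjusted p under 0.05 there were 914 probe sets, against 294.1 by chance. The honey and control values did not overlap at 1236 probe sets (21.0%, chance 10%), including all 63 that were called. Of the 63, 57 were PAO1 genes, 46 higher and 11 lower. The other 6 were 2 intergenic probe sets and 3 tRNA probe sets, all lower, and 1 probe set from another strain, which was higher. That probe set, Pae_M57501cds, rose by 0.58 ± 0.10 log2 units (limma adjusted p = 0.035) and was above background on every array. Its gene was not identified here, and the gene lists held PAO1 probe sets only.

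**Figure D1:**
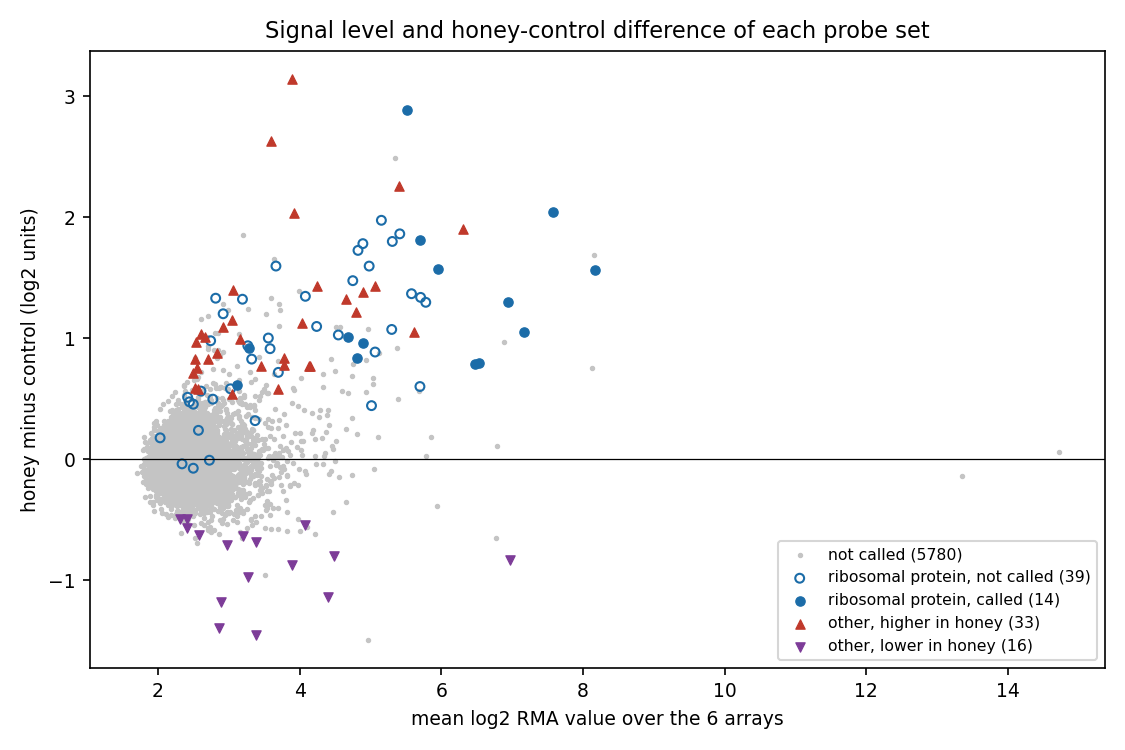
Each point is 1 of the 5882 probe sets, by its mean log2 RMA value over the 6 arrays (x axis) and the honey minus control difference in log2 units (y axis), with the 53 ribosomal protein probe sets in blue. The 47 probe sets called higher include 14 for ribosomal proteins, 5 of which turned to a lower value under cyclic loess, and the 16 called lower hold none.

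Among genes with a symbol, the largest rise was that of rpmI, for ribosomal protein L35, at 7.41-fold (2.89 ± 0.56, adjusted p = 0.046). It was 2.14 log2 units without honey replicate 2 and 2.06 under cyclic loess (adjusted p = 0.074). aceE, for the E1 component of pyruvate dehydrogenase, was not above background on any control array and rose at least 4.46-fold (adjusted p = 0.042). That bound was 2.74-fold without honey replicate 2. The catabolic ornithine carbamoyltransferase gene arcB rose by 2.04 ± 0.36 log2 units and was above background on 2 of the 3 control arrays. gatC, for a subunit of a tRNA-dependent amidotransferase, rose 2.70-fold (log2 difference 1.43, and 0.81 under cyclic loess, adjusted p = 0.083). etfB, for the beta subunit of the electron transfer flavoprotein, rose 2.60-fold. liuB, of leucine and acyclic terpene catabolism, rose at least 1.99-fold. Of the genes known only by locus tag, PA0284 rose at least 6.52-fold and PA3572 rose 3.75-fold (log2 difference 1.91, and 0.72 under cyclic loess, adjusted p = 0.11), with PA3309 between them. The bound of PA0284 was 4.55-fold without honey replicate 2.

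Only 6 genes with a symbol fell. dhcA, the partner subunit of dhcB, had a difference of -1.46 ± 0.24 and was above background on 2 of the 3 honey arrays. atoB, for an acetyl-CoA acetyltransferase, lies next to them (PA1999 to PA2001) and was at least 1.74-fold lower. capB was at least 1.84-fold lower (adjusted p = 0.012). fliE had a difference of -0.71 ± 0.09, and nalC, for a repressor acting on the MexAB-OprM efflux system, a signal difference of -0.62 ± 0.10, above background on 2 control arrays and 0 honey arrays. Of the locus-tag genes PA4606 fell by 0.80 log2 units and PA0988 by 0.64. PA2408, above background on 1 control array only, was called lower. PA3309 was the 1 named gene of the 28 called that kept its call whichever array was left out, with adjusted p up to 0.0023.

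**Figure D2:**
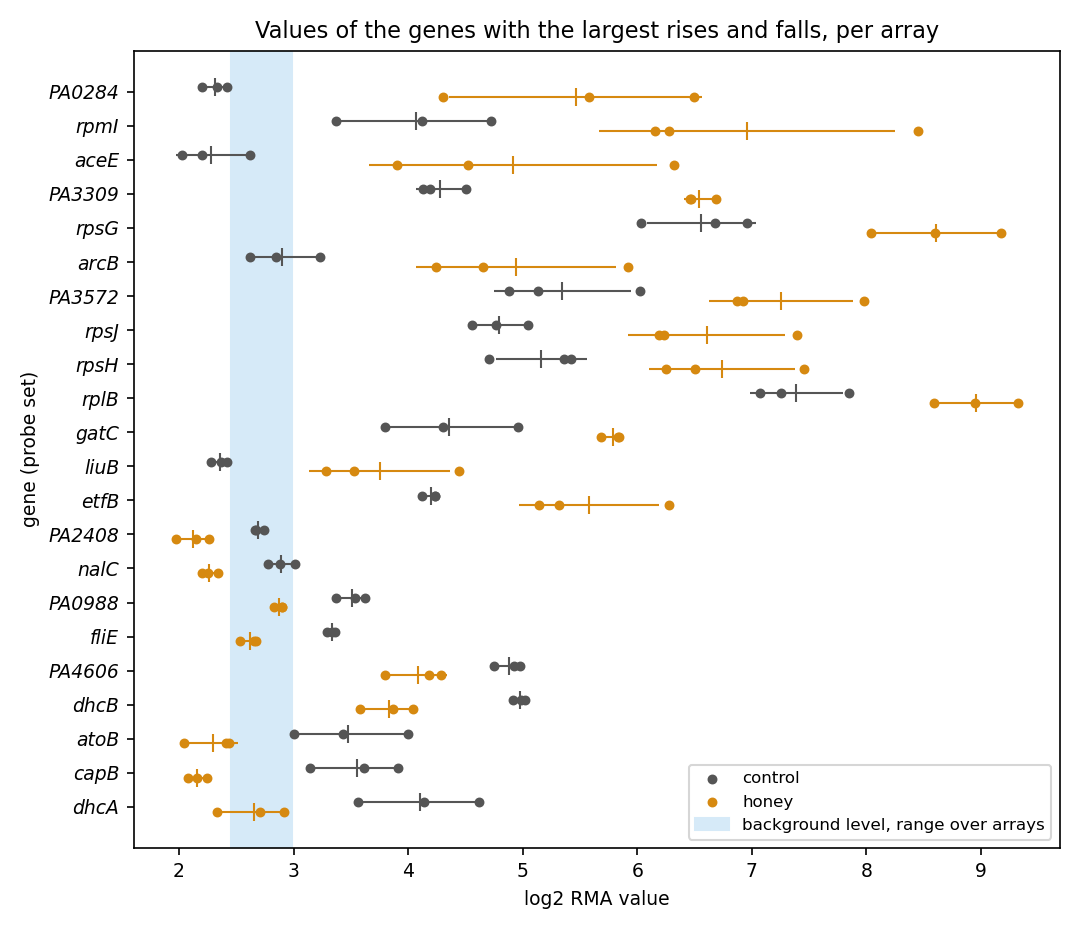
Log2 RMA values (x axis) of the 22 genes with the largest rises and falls among those called (y axis), with 1 point per array, a tick at the group mean and a bar of 1 SD (n = 3). The shaded band is the range of the background level over arrays, 2.46 to 2.99; aceE, liuB and PA0284 in control and capB, atoB, nalC and PA2408 in honey were not above the level of any of their arrays, and rplB turned to -0.45 under cyclic loess.

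Of the 53 ribosomal protein probe sets, 42 were above background, 14 rose, 39 were not called, and 40 rose when adjusted over the list alone. The number that rose was 1 under cyclic loess, 2 with trend and robust variance and 0 without moderation. It was 1, 7 and 0 without control replicates 1, 2 and 3, and 4, 18 and 11 without honey replicates 1, 2 and 3. The examples with the largest differences after rpmI were rpsG (2.05 ± 0.29), rpsJ (1.82 ± 0.29) and rpsH (1.58 ± 0.30). Under cyclic loess they had 0.29, 0.90 and 0.54, none called. rplB rose by 1.56 ± 0.22, but under cyclic loess it and 4 others chosen after their values were seen, rplE, rplV, rpsS and rplW, turned to values between -0.52 and -0.18, none called. The camera adjusted p of the list was 3.5e-33 (adjusted p = 0.44 with an estimated correlation), and the list median under cyclic loess was 0.55. Without honey replicate 2 the list median was 0.71 with the deposited scaling. The median value of the list was 3.37, 4.30 and 3.87 in control replicates 1, 2 and 3. In honey replicates 1, 2 and 3 it was 4.83, 5.55 and 4.37, so control replicate 2 and honey replicate 3 were close. Over the 6 arrays these medians had the same order as the number of probe sets above 5, which includes ribosomal protein probe sets. None of the 15 translation factor probe sets was called over all probe sets and 2 rose when adjusted over the list alone; the list was called higher with a median of 0.21 (camera adjusted p = 5.6e-05; adjusted p = 0.44 with an estimated correlation). Its largest differences were 1.23 ± 0.51 for infA (0.50 without honey replicate 2) and 1.20 ± 0.25 for fusA1, elongation factor G (adjusted p = 0.067). The 22 aminoacyl-tRNA synthetase probe sets held 0 called genes and 0 when adjusted over the list alone, with a median of 0.17 (camera adjusted p = 0.018; adjusted p = 0.44 with an estimated correlation). That call ended without control replicate 1 (0.068), without honey replicate 2 (0.065) and with the dimmest 25% (0.095) or 50% (0.27) of probe sets left out, and the largest differences were 0.52 for valS and 0.38 for lysS.

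In the list of 11 arginine deiminase and Anr-linked probe sets, Anr being the oxygen-sensing regulator of anaerobic genes, 3 rose, 8 were not called, and 7 rose when adjusted over the list alone. The 3 were PA3309, arcB and PA4352, another universal stress protein gene (1.00 ± 0.15, above background on 1 of 3 control arrays). The list median was 0.57 (camera adjusted p = 1.9e-08; adjusted p = 0.44 with an estimated correlation). In NADH dehydrogenase I, the proton-pumping entry point of the respiratory chain, 2 of 13 probe sets rose, nuoK by 1.12 ± 0.13 and nuoI by 0.78 ± 0.12, and 8 rose when adjusted over the list alone. The median was 0.56 (camera adjusted p = 3.1e-08; adjusted p = 0.44 with an estimated correlation). None of the 17 terminal oxidase probe sets was called, and 2 rose when adjusted over the list alone: ccoO2 and ccoP2, subunits of a high-affinity cbb3 oxidase, had differences of 2.49 ± 0.68 (adjusted p = 0.13) and 0.92 ± 0.24 (adjusted p = 0.12). For ccoO2 the difference was 1.60 without honey replicate 2 and 1.74 under cyclic loess, and for ccoP2 0.16 under cyclic loess. None of the 33 denitrification probe sets was called, also when adjusted over the list alone, with nirC at 0.53 ± 0.24. nirS, nitrite reductase, was not above background on any control array and did not pass the test (adjusted p = 0.12). Its bound was 1.75-fold higher in honey, and 1.24-fold without honey replicate 2. The 9 ATP synthase probe sets had a median of 0.05 and no call, with atpH at 0.31 and atpI, above background on 2 control arrays and 0 honey arrays, at -0.26.

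Of the lists for carbon and building-block metabolism, 5 were called higher by camera with few or no single genes. Glucose uptake and Entner-Doudoroff had 1 rise among 25 probe sets, PA2323 at 0.71 ± 0.14, above background on 2 honey arrays and 0 control arrays, and 2 rises when adjusted over the list alone (camera adjusted p = 0.041; adjusted p = 0.46 with an estimated correlation). That call ended without control replicate 1 (0.13), control replicate 3 (0.21) or honey replicate 2 (0.11), under cyclic loess (0.086), with array weights (0.070) and without the dimmest 25% (0.063). The tricarboxylic acid and glyoxylate cycles had 0 called of 20 and 2 rises when adjusted over the list alone, a median of 0.19, and sucB at 0.59 ± 0.15 (camera adjusted p = 0.00081; adjusted p = 0.44 with an estimated correlation); without honey replicate 2 the camera adjusted p was 0.053. sucC was not above background on any control array and did not pass the test (adjusted p = 0.12). Its bound was 1.41-fold higher in honey, and 1.15-fold without honey replicate 2. The sulfate starvation list had 0 called of 24, also when adjusted over the list alone, with PA3450 at 1.65 ± 0.51 (0.90 without honey replicate 2, adjusted p = 0.012) and cysD at 1.28 ± 0.39 (camera adjusted p = 0.018; adjusted p = 0.44 with an estimated correlation), and lost the call without control replicate 2 (0.056), without honey replicate 2 (0.080) and without the dimmest 50% (0.14). Amino acid biosynthesis had 0 of 54 called, also when adjusted over the list alone, with trpG at 0.90 and dapA, above background on 2 honey arrays and 0 control arrays, at 0.57 (camera adjusted p = 0.045; adjusted p = 0.44 with an estimated correlation). Purine and pyrimidine synthesis had 0 of 22 by both counts, with guaB at 0.75 and guaA at 0.60 (camera adjusted p = 0.019; adjusted p = 0.44 with an estimated correlation). The amino acid call ended without control replicate 1 (0.17), control replicate 3 (0.13), honey replicate 2 (0.13) or honey replicate 3 (0.070), under cyclic loess (0.10), with array weights (0.070) and without the dimmest 25% (0.13) or 50% (0.15), and the purine call without control replicate 1 (0.16) or honey replicate 2 (0.17). In amino acid catabolism, which camera did not call, liuB rose, and 7 genes rose and 3 fell when adjusted over the list alone. The 4 fructose phosphotransferase probe sets, for uptake of a main sugar of honey, held no call, with fruI, above background on 1 control array only, at 0.32 and fruK at -0.25.

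The flagellum list was the 1 list called lower. Of its 43 probe sets 12 were above background, fliE, a hook-basal body component, fell (above background on 1 of 3 honey arrays), 42 were not called, and 3 fell when adjusted over the list alone. The list median was -0.15 (camera adjusted p = 0.045; adjusted p = 0.44 with an estimated correlation). The call ended without control replicate 2 (0.17), control replicate 3 (0.13), honey replicate 2 (0.089) or honey replicate 3 (0.12), under cyclic loess (0.063) and without the dimmest 25% (0.095) or 50% (0.15). The regulators fleQ (0.12 ± 0.15), fleR (-0.15 ± 0.14), fleN (0.02 ± 0.12), fliA (0.16 ± 0.16) and flhF (-0.17 ± 0.11) were not called. Neither fleR nor fliA was above background on all arrays of a group. The PAO1 probe set of the flagellin gene fliC was not above background on any array (0.00 ± 0.11). As the strain differs from PAO1, this does not show that its flagellin gene was silent or unchanged. Probe sets from other strains were not in the list, so a flagellin gene of another type was not examined. None of the 29 chemotaxis probe sets was called, and in the 30 type IV pilus probe sets pilG, a twitching motility response regulator, rose at least 1.13-fold, the 1 gene of that list to do so also when adjusted over the list alone.

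Lists for virulence, iron, stress and the cell envelope held few calls, and many of their probe sets were not above background. Alginate biosynthesis had 1 of 13 probe sets above background and no call, with algD, above background on 1 control array only, at 0.15 ± 0.09. No gene was called among 22 for Pel and Psl exopolysaccharides, 16 for quorum-sensing regulators and signal synthesis, 16 for quorum-sensing-controlled exoproducts, 10 for phenazines, 11 for type II, 40 for type III and 18 for type VI secretion, 22 for pyoverdine, 14 for pyochelin and 24 for other iron acquisition. Of these, the exoproduct list alone held genes past the threshold when adjusted over the list alone, 2 that fell: hcnC (-0.38 ± 0.10) and chiC (-0.38 ± 0.09), neither above background on all arrays of a group. Of 17 heat shock and chaperone probe sets the sigma factor gene rpoH rose by 1.05 ± 0.20, a call kept in 1 of the 6 runs with an array left out and lost under cyclic loess (0.18), and 2 probe sets rose when adjusted over the list alone. Oxidative stress defence had 0 of 19 called and 2 rises when adjusted over the list alone. They were sodB, iron superoxide dismutase, at 0.79 ± 0.18 (adjusted p = 0.089) and PA0962 at 0.48 ± 0.11, not above background on any array. No call was made among 6 probe sets for methylglyoxal and aldehyde detoxification, 32 for RND efflux, 29 for osmoadaptation, 14 for the SOS response, 37 for R and F pyocins and 14 for the Pf prophage. The same held for 28 of cell division and peptidoglycan synthesis, 12 outer membrane proteins, 16 of the cationic peptide response, 14 of lipid A and core, 14 of fatty acid synthesis, 16 of phosphate and 22 of zinc starvation, except that oprG, of the outer membrane list, rose when adjusted over the list alone (0.55 ± 0.13). The porin gene oprF had a difference of 0.32 ± 0.33, which ran from -0.20 to 0.56 over the alternative settings, and was above background on 1 honey array only. Across the 33 lists that camera did not call, adjusted p ran from 0.27 to 0.98; median, mean and camera direction differed in sign in 13 of them.

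**Figure D3:**
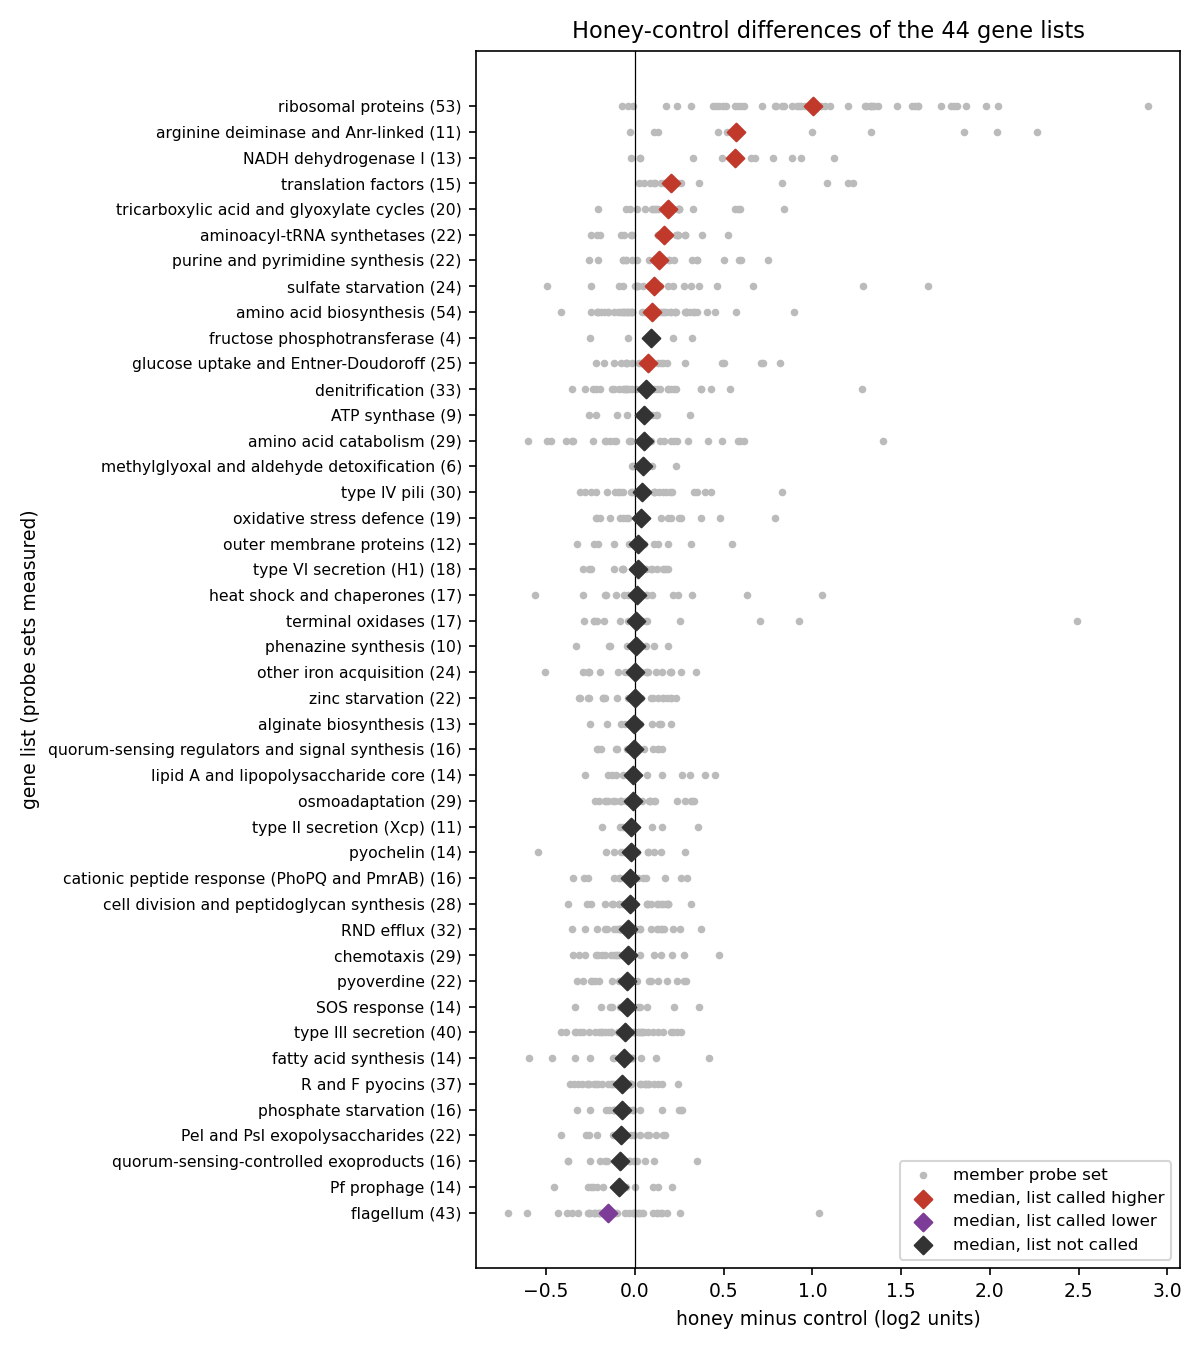
Honey minus control differences in log2 units (x axis) of the members of the 44 gene lists (y axis, with the number of probe sets measured), with 1 grey point per probe set and a diamond at the median. Ribosomal proteins (1.00), arginine deiminase and Anr-linked genes (0.57) and NADH dehydrogenase I (0.56) lie farthest right, and the flagellum list (-0.15) farthest left; these and the 7 other called lists lost their calls with an estimated correlation.

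With each array left out in turn the number of probe sets changed was 8 without control replicate 1, 24 without control replicate 2, 2 without control replicate 3, 19 without honey replicate 1, 70 without honey replicate 2 and 38 without honey replicate 3. All 63 kept their direction in each of these, which was fixed in advance because their honey and control values did not overlap. Camera calls at the preset correlation of the ribosomal protein, translation factor, arginine deiminase and NADH dehydrogenase lists held in each of these runs. With all arrays, these calls were lost with an estimated correlation (camera adjusted p = 0.44). With only the probe sets above background, a setting chosen after seeing the data, 8 lists lost their calls at the preset correlation. The ribosomal protein, arginine deiminase and NADH dehydrogenase lists kept theirs at that correlation.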

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

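The 3 settings on background level, its centring and the joint removal of 2 arrays were chosen after seeing the data. The replicate block gave 84 probe sets, 71 higher (43 by at least 2-fold); 53 of the 63 calls were among them, and 27 of its calls were ribosomal proteins. Same-numbered arrays' deviations correlated at 0.10, 0.17 and -0.02, and 3 of the 6 arrays (control 1, control 3 and honey 3) correlated best with another number. Cyclic loess called 29, 15 higher (6 by 2-fold) and 14 lower (8 by 2-fold), 26 shared, with 0 lists lower; rplB reversed to -0.45, and 5 of 63 calls changed sign. Trend and robust variance called 31, 21 higher (11 by 2-fold), 10 lower. Without moderation 1 was called, lower, with 0 higher and 0 by 2-fold either way (701 at unadjusted p under 0.05); camera was not run there. Leaving out each array gave 2 to 70 changed, 2 to 59 higher (2 to 28 by 2-fold), 0 to 11 lower (0 to 5 by 2-fold), 4 to 10 lists higher and 0 to 1 lower. Lists lower were 0 without the dimmest 25%, 0 without the dimmest 50% and 0 above background, where 3 were higher. Without honey replicate 2 and control replicate 1, 7 fell by 2-fold and 4 lists were higher. With an estimated correlation 0 lists were higher and 0 lower, as with fry (unadjusted p under 0.05 for 3 and 11 lists). The causes were not tested, except that fewer arrays or probe sets were used. In the named genes 1566 other values stayed on their side of the threshold, 165 lost and 13 gained a call; in the lists 708 stayed and 67 lost it. Signal over background limits the rest: 997 of 5882 probe sets were above it.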

Other observations

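The tests of honey replicate 2, of small RNA loss and of the dim and bright ribosomal protein genes were chosen after the result was seen, as were all genes named in this part. Outside the lists, both intergenic probe sets that were called fell. The one between PA4726 and PA4727, where the PAO1 annotation places 3 non-coding RNAs (PA4726.1, crcZ and PA4726.2) that it does not tell apart, fell by 0.87 ± 0.12 log2 units (limma adjusted p = 0.015, no overlap between groups). The probe set of the opposite orientation was not called. The one between PA3463 and PA3464, with no annotated RNA, fell by 0.83 ± 0.15 (2.32 under cyclic loess), and both were called under cyclic loess too. Further genes that rose were faoA of fatty acid oxidation (at least 1.20-fold), the nitrate response regulator narL (at least 1.64-fold), the acetate kinase gene ackA (0.77 ± 0.14), the D-amino acid dehydrogenase gene dadA (1.32 ± 0.25) and the transcription factor gene nusA (0.77 ± 0.15).

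Of the 53 ribosomal protein probe sets 14 were called higher in honey, and 1 under cyclic loess. The list's camera call was lost with an estimated correlation (adjusted p = 0.44). Bright probe sets were higher as a whole: the median difference of the 24 outside the list with a mean value above 5 was 0.59. A larger signal of all bright probe sets is argued against as the whole cause, since the list's median of 1.00 lay at percentile 100 of 10000 random lists matched on mean value (95% between 0.03 and 0.34). Members of the random lists were drawn independently, so that range can be too narrow for genes that move together. For the 34 members with a mean value of 5 or below the percentile was 100 (matched lists up to 0.17), but for the 19 above 5 (percentile 99.77) the matched probe sets were dimmer, 5.46 against 6.003, so the explanation stays open there and may account for part of their rise. Cyclic loess, which removes a trend with brightness, took the median of the 34 from 0.92 to 0.64 (32 above 0) and that of the 19 from 1.34 to 0.34 (12 above 0). Because the 19 stood beside only 24 others above 5, cyclic loess would also lower a real rise of theirs. Their smaller median under it therefore does not tell the explanations apart. Honey replicate 2 alone is argued against by the list median of 0.71 without it. With control replicate 1 left out as well, a setting chosen after seeing the data, the list median was 0.58. The 155 other short genes above background had a median of 0.053, which argues against a bias by gene length across them. They were not matched on signal level, so a bias limited to bright short genes stays open. A shared change of the ribosomal protein genes with the treatment remains a hypothesis.

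Of 18 tRNA probe sets 3 fell, those for Phe (-0.97), Val (-0.68) and Asn (-0.50), the last above background on 1 control array and 0 honey arrays. Loss of small RNAs from the honey extracts was tested on the 10 tRNA and 5S ribosomal RNA probe sets above background, of which 70% were lower; the 3 higher ones, with no call and overlapping groups, do not exclude it, so a loss of small RNAs and a change in the cells cannot be told apart.

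Genes close together on the PAO1 map moved together, a hypothesis set out before it was tested. The 8 non-ribosomal genes between PA4237 and PA4277, inside ribosomal protein operons, had a median difference of 0.75, at percentile 100 of matched lists (up to 0.35), and 1 of them, rpoC, rose (0.84 ± 0.13), while secE was at -0.08. Over 194 pairs of neighbouring genes above background, outside the ribosomal protein list, the differences correlated at r = 0.39 across genes, which are not independent replicates, against an upper bound of 0.14 for the central 95% of 10000 permutations. The permutations did not match signal level, and neither test separates the treatment from variation between cultures that neighbouring genes share. Changes at the level of operons therefore remain a hypothesis.

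With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The real split gave 63 probe sets and each of the 9 others 0; for gene lists the real split gave 11, and of the others 1 also gave 11 and the rest 0 to 9.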
